A study of Homo sapiens with 4 samples.

How the data were processed

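The data were 4 libraries of chromatin-associated RNA from A549 cells, a human non-small cell lung cancer line. The cells carried a stable knockdown of METTL3, the catalytic subunit of the main mRNA m6A methyltransferase, and a doxycycline-inducible lentiviral rescue with either the wild-type protein (METTL3-WT, 2 libraries) or the form the labels call METTL3-3KR (2 libraries). Groups and replicate numbers were taken from the labels. Per the labels' protocols, expression was induced for 48 h with 2 µg/ml doxycycline, the chromatin fraction was isolated, ribosomal RNA was depleted, and RNA was fragmented at 94 °C for 30 s. RNA was then taken through GLORI, in which glyoxal protects guanosine and nitrite deaminates unmodified adenosine for 8 h at 16 °C. An unmodified A is therefore read as G, whereas an N6-methylated A is still read as A, and the share of A among A and G reads at a position is the m6A level. GLORI also leaves other N6-methylated adenosines unconverted, such as m6Am. Nothing in the labels says that the 2 libraries of a genotype came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

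The submitters' processing notes name Trim Galore 0.6.7, STAR 2.7.10b, Bowtie 1.3.1 and SAMtools, with the hg38 build and no order of steps. The site caller is not given in the sources used here. Each library came as 1 table of called sites with position, strand and, for part of the sites, a gene name. Per the file headers, the deposited counts are A reads and A plus G reads at each site, and the level is a fraction, the A reads divided by the A plus G reads. A conversion fraction per gene, or per chromosome strand for sites with no gene, and a coverage value (a signal) per gene are also given per the file headers, and how that coverage was averaged is not given in the sources used here. The deposited p-values and adjusted p-values are the authors' own. Tested on the tables, every listed site had at least 15 A plus G reads, at least 5 A reads and a level of at least 0.1, and no unadjusted p was above 0.004. A one-sided binomial p computed from the reads and the conversion fraction lay within 10% of the authors' value for 94.9% to 99.6% of sites per library. A site missing from a table may thus be unmethylated, thinly covered or below one of these limits, and levels carry the unconverted background. Intervals given for shares are 95% Wilson intervals and cover counting error only, since the reads carry no molecular identifiers that are described.

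Sites were matched between libraries by chromosome, position and strand. Of the 12761 gene names, 12149 matched a RefSeq symbol and 228 a RefSeq synonym on GRCh38.p14, the same assembly as hg38, and these gave gene spans and types. The strand of a gene was taken from its listed sites. Region classes were built from the gene name and these spans: within 1 kb of a transcription start (the outer gene end), upstream antisense (within 2 kb upstream of a protein-coding start, on the other strand), inside a gene with no gene assigned, and distal intergenic (over 2 kb from any gene). No reference genome sequence or transcript model was used, so sequence motifs, exons, introns and untranslated regions were not analysed here, and the planned restriction to DRACH motifs was not run. An enhancer map was not used here.

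Levels were compared at sites listed in all 4 libraries with at least 20 A plus G reads in each. The main test was the edgeR 4.0.16 quasi-likelihood F test on A and G counts in R 4.3.3, with a coefficient per library, 1 for A against G and 1 for the effect of genotype on that ratio, so that coverage cancels within a site. It was run per site and per gene, on reads summed over the shared sites of a gene. Changes are given as log2 odds, METTL3-3KR over METTL3-WT, with the Benjamini-Hochberg adjusted p and a threshold of 0.05. Lists and region classes were compared with all other genes or sites by camera in limma 3.58.1 on the empirical logit with a pseudocount of 0.5, with a preset correlation of 0.01 and again with an estimated one. The estimated version takes its degrees of freedom from the 4 libraries and can hardly pass, so a call lost with it says little. For medians per library only an exact permutation test was considered, and with 2 against 2 libraries its two-sided p is at least 0.333, so it was not run and no parametric test was used. On simulated counts for the 5053 genes tested, with the overdispersion seen between replicates, the edgeR test recovered 68% of genes changed by 1 log2 unit of odds and 18% of those changed by 0.5, and 7.53% of its calls were false. At 10 times that overdispersion these values were 15%, 1% and 30.4%. For the 21547 sites the lower overdispersion gave 22%, 0% and 12%, so most changes of these sizes at single sites would be missed. The changed genes and sites were drawn from those with a mean of at least 50 reads per library. Recovery at lower coverage was not simulated.

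Genes were named by a rule fixed before the data were examined. METTL3 was always named. Among genes with an adjusted p under 0.05, both METTL3-3KR libraries on the same side of both METTL3-WT libraries and at least 200 reads in every library, the 8 largest falls and the 8 largest rises in odds were named. For sites, with at least 50 reads, the 5 largest falls and rises in level were named, 1 per gene, and for each of the promoter, upstream antisense and distal intergenic classes the 3 sites with the smallest adjusted p. Up to 4 members with the smallest p were taken from each fixed list, whose members were matched by symbol, or by a synonym that is no other gene's name. The 18 lists held m6A writers, m6A readers and erasers, acetyltransferases with deacetylases and acetyl-lysine readers, histone methylation and Polycomb genes, nuclear long noncoding RNAs, immediate-early and short-lived transcription factor genes, NRF2 targets, lung cancer growth signalling, TGF-beta and epithelial-mesenchymal transition, hypoxia and glycolysis, interferon and NF-kB response, DNA damage response, splicing factors, cell cycle and mitosis, replication-dependent histones, alveolar and lung epithelium, and markers of fibroblasts and of blood and endothelial cells. Alternatives tried were other coverage minimums (15 and 50), DESeq2 1.42.0, Fisher's exact test on summed reads, quasi-binomial regression, limma, a replicate block, centring on the median change, subtraction of the unconverted background, thinning to equal coverage, a level minimum of 0.2, other promoter windows (500 bp and 2 kb), and leaving out each library. Restriction to protein-coding and long noncoding RNA genes, a stricter P of the authors (at most 1e-10), minimums of 10 and 20 A reads for listed sites, a subset of well-measured sites and the tests on gene coverage were added after the data were seen. Coverage per gene was compared with limma on log2 values centred on each library's median. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.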

Results

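m6A was mapped at single-base resolution on chromatin-associated RNA of A549 lung cancer cells in which METTL3 had been knocked down and replaced by METTL3-WT or METTL3-3KR, in common notation a form with 3 lysines changed to arginine. The series title places the question at enhancer and promoter RNAs and ties it to acetylation of METTL3 and of histone H3 lysine 27. There were 2 libraries per genotype. The METTL3-WT libraries listed 206846 and 340433 sites carrying 10152674 and 15224712 A plus G reads, and the METTL3-3KR libraries listed 156519 and 158334 sites carrying 8718603 and 9001153 reads. At the 24352 sites listed in all 4 libraries, median coverage was 56.5 and 53 reads in METTL3-WT and 56 and 61 reads in METTL3-3KR.

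METTL3 RNA itself (chromosome 14, 21498138 to 21511340) was more methylated in the METTL3-3KR cells. Over its 12 shared sites the m6A level was 27.2% ± 0.288 in METTL3-WT and 33.1% ± 0.891 in METTL3-3KR (SD, n = 2 each), a rise of 0.41 ± 0.08 log2 odds (SE, edgeR adjusted p = 2.02e-05) on 3038 to 6190 reads per library, with 8 sites higher and 4 lower. The coverage value of METTL3 was 257 and 224 in METTL3-WT and 347 and 464 in METTL3-3KR, a 1.68-fold higher mean (limma adjusted p = 0.0142). Reads of the rescue transgene and of the endogenous transcript cannot be separated in these tables, so both values may mix them. Without METTL3-3KR replicate 2 the METTL3 rise was 0.36 log2 odds and its call was lost (adjusted p = 0.0702).

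Strongly methylated positions were found in both genotypes, including those near promoters and outside genes. Of the 3311 sites with a level of at least 50% and at least 50 reads in both METTL3-WT libraries, 97.6% (Wilson interval 97.0% to 98%) were also listed, at a level of at least 0.1, in both METTL3-3KR libraries. In the reverse direction this held for 94.8% (94.0% to 95.4%) of 3897 sites. Within 1 kb of a transcription start the shares were 99.1% (97.9% to 99.6%) of 545 METTL3-WT sites and 98.1% (96.6% to 98.9%) of 566 METTL3-3KR sites. For upstream antisense sites, a class that also takes in sites of neighbouring genes on the other strand, they were 96.3% (87.5% to 99%) of 54 and 94.4% (84.9% to 98.1%) of 54. For distal intergenic sites they were 94.1% (85.8% to 97.7%) of 68 and 98.8% (93.3% to 99.8%) of 80. Small nuclear RNA copies were not set apart in these shares. Among shared sites with at least 20 reads, 38 in U2 and 256 in U6 copies had a level of at least 80% in every library. METTL3 is not known to modify these, and such short genes lie within 1 kb of their own start. How much of each share they make up was not counted.

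The long site lists differed mainly in positions with no gene assigned. METTL3-WT libraries listed 147635 and 268639 such positions and METTL3-3KR libraries 103628 and 100710, against 59211, 71794, 52891 and 57624 positions in genes. Few unassigned positions recurred: 4.85% and 2.66% of those of the METTL3-WT libraries were listed in the other METTL3-WT library, and 7.28% and 7.49% for METTL3-3KR. The unconverted background was 1.3% and 1.75% in the METTL3-WT libraries and 0.969% and 0.982% in the METTL3-3KR libraries. These are medians over autosome strands of the values for sites with no gene. Between 82.5% and 84.4% of unassigned positions rested on 5 to 7 A reads in every library. Sites listed in both libraries of a genotype and neither of the other numbered 4430 for METTL3-WT and 5614 for METTL3-3KR. By class these were 429 and 425 sites within 1 kb of a start, 100 and 71 upstream antisense sites, 128 and 255 distal intergenic sites, and 1671 and 1348 unassigned sites inside a gene on its own strand. After thinning to the lowest depth the order of the totals turned, with 4490 for METTL3-WT and 4429 for METTL3-3KR. These counts need both replicates. With 1 library left out, METTL3-WT counts ran from 6865 (without METTL3-3KR replicate 1) and 7406 (without METTL3-3KR replicate 2) to 166117 and 300685 (without METTL3-WT replicate 2 or 1). The matching METTL3-3KR counts were 116040, 115796, 9089 and 10090.

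**Figure D1:**
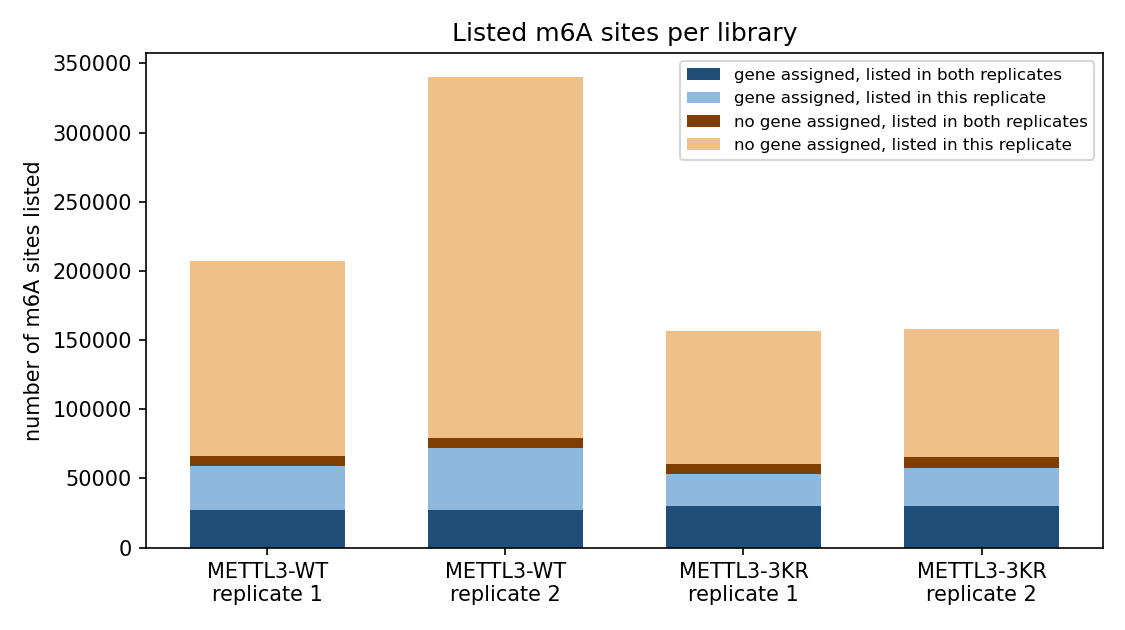
Stacked bars give the number of m6A sites listed in each of the 4 libraries and are split by whether a gene was assigned and whether the other replicate of the genotype listed the site too. Positions with no gene assigned that recurred in the other replicate made up 7155 sites for METTL3-WT and 7539 for METTL3-3KR.

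At sites measured in all libraries, levels were slightly higher in METTL3-3KR. The median level over 21547 shared sites with at least 20 reads was 36.0% and 36.4% in the METTL3-WT libraries and 38.0% and 38.1% in the METTL3-3KR libraries, a difference of 1.86 percentage points, larger than the spread between replicates (SD 0.257 and 0.0783 points). Promoter-proximal sites (n = 2130) had medians of 40.0% and 40.6% against 42.7% and 41.4%, upstream antisense sites (n = 373) 31.4% and 32.1% against 35.5% and 33.3%, and distal intergenic sites (n = 380) 42.2% and 42.8% against 43.0% and 44.9%. Unassigned sites inside a gene on its own strand (n = 2059) went from 26.1% ± 0.535 to 28.8% ± 0.188 (SD, n = 2). Both METTL3-3KR libraries lay above both METTL3-WT libraries in each of these classes, the most extreme order possible, yet 2 against 2 libraries cannot bring an exact permutation test under 0.05. The METTL3-3KR mean was lower for pseudogene sites (n = 973, 70.3% ± 0.161 and 69.9% ± 0.840), for unassigned sites inside genes on the opposite strand (n = 126, 70.4% ± 5.73 and 69.9% ± 1.89) and for small or structural RNA gene sites (n = 33, 37.3% ± 2.63 and 37.0% ± 3.87). In these classes the libraries of the genotypes overlapped, as they did or touched for sites in other or unmatched genes (n = 82), inside genes of unknown strand (n = 372) and between genes within 2 kb of one (n = 228). No class passed camera against the other sites (lowest adjusted p = 0.777 with the preset correlation and 0.493 with an estimated one). The preset correlation of 0.01 was above every estimate for these classes (at most 0.00678), which makes the test strict for large classes. The estimated version can hardly pass with 4 libraries. Neither result therefore shows that the classes changed alike. The promoter difference of 1.72 points became 0.964 points with a window of 500 bp and 3.72 points with coverage-weighted levels, and the distal intergenic difference of 1.49 points became 6.08 points at a coverage minimum of 50 and 0.438 points with coverage-weighted levels. At promoters, weighting gives great weight to U2 copies such as RNU2-23P, with 352407 to 494275 reads per library at 1 site. The 3.72 points therefore need not reflect other promoter sites. The promoter medians also take in U2 and U6 copies, of which 43 and 472 were tested at the gene level. What part these copies have in the promoter medians was not tested.

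**Figure D2:**
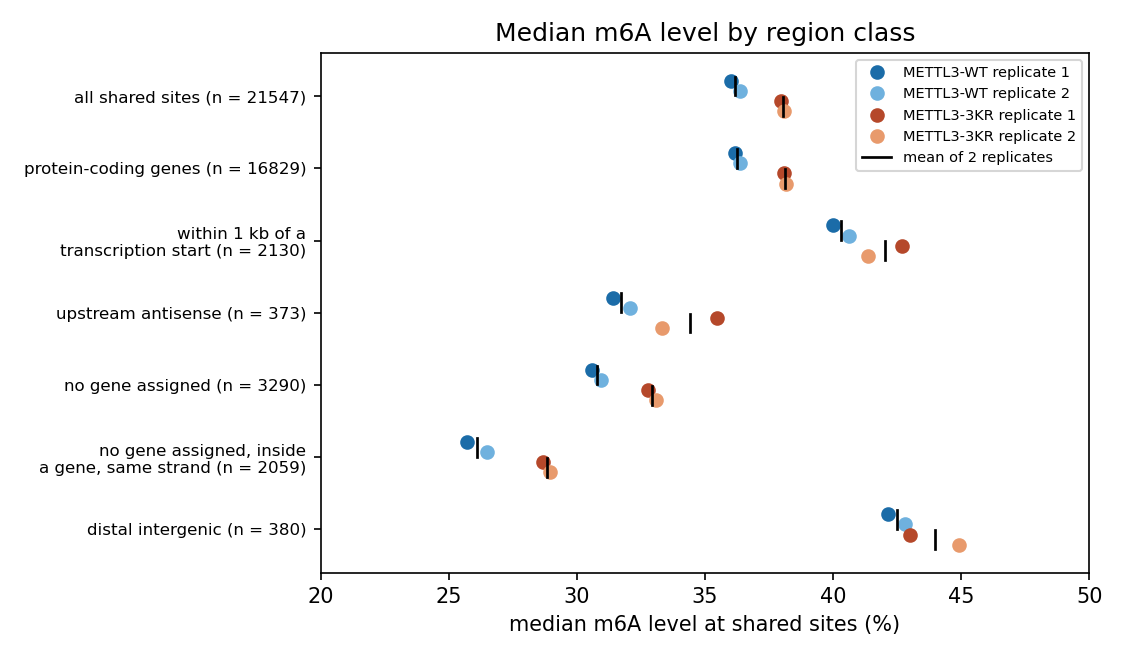
Points give the median m6A level (%) of each library at shared sites of each region class and black bars the mean of the 2 replicates of a genotype. The axis runs from 20 to 50%, and METTL3-3KR points lie to the right of METTL3-WT points in every class shown. Sites within 1 kb of a transcription start include U2 and U6 small nuclear RNA copies.

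Single sites with the largest changes lay in NR4A1, TIPARP, KLF6, STARD4 and SRSF6, among others. In NR4A1, an orphan nuclear receptor induced within minutes of stimulation, the level at position 52054642 of chromosome 12 (plus strand) was 29.6% ± 0.0516 in METTL3-WT and 60.5% ± 3.30 in METTL3-3KR (SD, n = 2), on 406 to 858 reads per library. In TIPARP, an ADP-ribosyltransferase gene induced by the aryl hydrocarbon receptor, the site at 156678335 of chromosome 3 rose from 46.4% ± 5.16 to 75.4% ± 2.91. In KLF6, a zinc finger transcription factor, the site at 3782003 of chromosome 10 rose from 30.1% ± 3.04 to 51.6% ± 0.234. Rises were also called at 27672495 of chromosome 6 in the tRNA gene TRS-CGA3-1 (20.3% ± 0.488 to 48.3% ± 14.1) and at an unassigned position, 32759315 of chromosome 21, inside a gene on its own strand (16.1% ± 2.37 to 42.8% ± 8.97). The tRNA site lay 36 bases from an annotated gene start, and which modification its A reads mark was not determined. The largest falls were in RNF19A (chromosome 8, 100258929, 49.8% ± 11.7 to 22.8% ± 0.743) and STARD4 (chromosome 5, 111499192, 46.5% ± 1.68 to 19.7% ± 4.41). Next came the splicing factor gene PRPF38A (chromosome 1, 52404602, 53.2% ± 2.22 to 30.7% ± 2.45) and SRSF6 (chromosome 20, 43461070, 38.4% ± 2.21 to 22.7% ± 0.298). CTPS1, a CTP synthase gene, followed (chromosome 1, 41012033, 28.4% ± 1.31 to 14.1% ± 3.31). The PRPF38A site lay 0 bases from an annotated gene start, and A reads cannot tell m6A from m6Am there. In all, edgeR called 58 sites higher and 12 lower in METTL3-3KR of 21547 tested. The median change over sites was 0.10 log2 odds, and centring on it gave 33 higher and 18 lower. A coverage minimum of 50, which tests fewer sites, gave 130 higher and 32 lower, and Fisher's exact test on summed reads 786 and 293.

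Among promoter-proximal sites 16 were called higher and 1 lower of 2130. The same 16 and 1 lay on the sense strand within 1 kb downstream of a start, a class that takes in short genes whole. Of all sites called higher, 13 were in pseudogenes and 2 in small or structural RNA genes. The promoter calls may thus lie in such genes, and how many of the 16 were U2 copies was not counted. Among upstream antisense sites 3 were called higher and 0 lower of 373, where 43 had an unadjusted edgeR p under 0.05. No distal intergenic site of 380 was called by edgeR, where 29 had an unadjusted p under 0.05. DESeq2, which gave no adjusted p for 20469 of all 21547 sites, and quasi-binomial regression and limma, which recovered 10% and 0% of simulated 1-unit changes at sites, called 0 as well, so these zeros say little. Fisher's exact test on summed reads, which ignores the spread between replicates, called 7 higher and 2 lower. The 3 promoter-proximal sites with the smallest adjusted p were in copies of the U2 small nuclear RNA. They were RNU2-23P (chromosome 11, 65147613, 92.3% ± 0.0909 to 94.4% ± 0.250), RNU2-3P (chromosome 15, 95745833, 93.2% ± 0.0467 to 95.1% ± 0.268) and RNU2-32P (chromosome 17, 41467985, 95.3% ± 0.00629 to 97.0% ± 0.0176). The leading upstream antisense entries were 2 sites in AMIGO2 transcripts, which run antisense to a neighbouring promoter, at 47078305 and 47078424 of chromosome 12 (92.1% ± 0.987 to 95.8% ± 0.408, and 91.1% ± 0.386 to 95% ± 0.18), followed by RNU2-17P. The distal intergenic site with the smallest adjusted p was at 27303825 of chromosome 6 (27.4% ± 5.65 and 10.5% ± 0.295, edgeR adjusted p = 0.0774). Next were 94519019 of chromosome 2 (13.2% ± 1.48 and 37.6% ± 14.9, adjusted p = 0.252) and 90686708 of chromosome 3 (24.1% ± 2.69 and 44.6% ± 17.2, adjusted p = 0.283). Site calls rested on all 4 libraries. Without METTL3-WT replicate 1 there were 27 higher and 7 lower, and without METTL3-WT replicate 2 there were 25 and 2. Without METTL3-3KR replicate 1 there were 29 and 6, and without METTL3-3KR replicate 2 there were 21 and 5. The NR4A1 site was called in each of these 4 fits, and the KLF6 and CTPS1 sites in none. Quasi-binomial regression and limma called 0 sites, where 1895 and 1675 had an unadjusted p under 0.05 against 1975 with edgeR.

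At the gene level, NR4A1 and ATF3, both stress- and signal-induced transcription factors, had the largest rises among called protein-coding genes with at least 200 reads in every library, and STARD4, SRSF6, MKLN1, PRKAA1 and DGKD the largest falls. NR4A1 (chromosome 12, 52022832 to 52059503) rose from 23.9% ± 0.0160 to 41.3% ± 1.79 over 10 sites, all of them higher (1.17 ± 0.09 log2 odds, edgeR adjusted p = 1.76e-38). ATF3 (chromosome 1, 212565407 to 212620777) rose from 28.1% ± 4.05 to 48.3% ± 2.41 over 3 sites (1.28 ± 0.18, adjusted p = 1.92e-10). STARD4 (chromosome 5, 111496033 to 111512535), a sterol transfer protein, went from 42.4% ± 2.13 to 26.5% ± 1.80 over 2 sites, its log2 odds falling by 1.02 ± 0.21 (adjusted p = 0.000163). SRSF6 (chromosome 20, 43457896 to 43464243), a serine- and arginine-rich splicing factor, fell from 45.0% ± 0.540 to 31.7% ± 2.98 over 3 sites, of which 1 was higher (adjusted p = 4.51e-09). MKLN1, encoding muskelin, fell from 26.5% ± 0.830 to 17.9% ± 1.14. PRKAA1, a catalytic subunit of AMP-activated kinase, fell from 36.8% ± 4.09 to 26.2% ± 0.815, and DGKD, a diacylglycerol kinase, from 36.4% ± 0.562 to 26.1% ± 3.05 (adjusted p = 0.0327 and 0.0489). At a coverage minimum of 50 the DGKD change went from -0.70 to -0.10 log2 odds and its call was lost.

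Multi-copy RNA filled the other places among the largest changes. The rises in RNU2-63P (56.3% ± 5.21 to 77.0% ± 2.43), RNU2-58P (79.3% ± 9.97 to 89.9% ± 1.26), and RNU2-34P (94.4% ± 0.685 to 97.3% ± 0.0144) each rested on 1 site of a U2 copy. So did those in RNU2-46P (93.6% ± 0.209 to 96.8% ± 0.0525), RNU2-17P (91.1% ± 0.449 to 95.4% ± 0.499) and RNU2-60P (93.1% ± 0.148 to 96.5% ± 0.403). Falls were called in the U6 copies RNU6-27P (89.5% ± 3.16 to 81.1% ± 0.654) and RNU6-25P (98.4% ± 0.155 to 97.4% ± 0.46) and in the pseudogene LOC110467533 on chromosome 2 (74.9% ± 1.08 to 62.1% ± 9.99). The LOC110467533 change went from -0.95 to -0.42 log2 odds without METTL3-3KR replicate 1, which ended its call (adjusted p = 0.549), and its coverage value was 0.332-fold that in METTL3-WT. The RNU2-58P change went from 1.2 to 0.49 without METTL3-WT replicate 2, and its call was lost. After background subtraction the changes of RNU2-34P, RNU2-46P and RNU2-60P went from 1.08, 1.03 and 1.03 to 0.38, 0.38 and 0.37, and that of RNU6-25P from -0.76 to -0.16, and only RNU2-60P kept its call. Such near-identical copies can exchange reads with each other and with the active genes, so the assignment to 1 copy is uncertain. As a group, 24 of the 43 U2 copies tested were called higher and 0 lower, while of the 472 U6 copies tested 2 were called higher and 6 lower. U2 carries a METTL4-dependent m6Am and U6 a METTL16-dependent m6A, so neither modification is known as a METTL3 product.

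Of 5053 genes tested, edgeR called 109 higher and 44 lower in METTL3-3KR, among them 74 and 33 protein-coding genes. The median change was 0.07 log2 odds, and centring on it gave 69 higher and 52 lower. The counts depended on every library. Without METTL3-WT replicate 1 they were 54 higher and 29 lower, and without METTL3-WT replicate 2 they were 57 and 19. Without METTL3-3KR replicate 1 they were 31 and 8, and without METTL3-3KR replicate 2 they were 40 and 18. NR4A1, ATF3, FOS, DUSP5, KLF6, DDX5, SRSF6, TXNRD1, RNU2-60P and RNU2-63P were called in all 4 of these fits. CCN1, DGKD, DUSP1, PFKP, RNU2-46P and RNU6-25P were called in none, and the other 17 of the 33 named genes whose calls were tested this way in 1 to 3. Limma called 0 genes, where 450 had an unadjusted p under 0.05 against 629 with edgeR, and DESeq2 called 48 higher and 14 lower.

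Immediate-early genes, which are transcribed within minutes of a signal and whose short-lived RNAs encode transcription factors and feedback phosphatases, formed the group with the clearest change. Of 35 genes on this list 23 were tested, 9 were called higher in METTL3-3KR and 0 lower, both over all genes and adjusted over the list alone, and 21 of the 23 had a positive change. FOS, a subunit of the AP-1 factor, rose from 31.2% ± 1.10 to 40.8% ± 1.65 over 10 sites (SD, n = 2). DUSP5, a nuclear phosphatase of ERK, rose from 45.0% ± 0.653 to 55.2% ± 2.35 over 10 sites, and KLF6 from 32.3% ± 2.49 to 45.0% ± 0.753 over 9 sites. The further members called were NR4A1, ATF3, DUSP6 (32.2% ± 0.394 to 41.8% ± 0.0794), NR4A2 (48.9% ± 10.0 to 75.0% ± 10.8), ZFP36L1 (30.6% ± 2.63 to 39.8% ± 0.617) and DUSP1 (30.4% ± 0.627 to 33.6% ± 0.738). Against all other genes the list moved up by camera with an adjusted p of 0.000174, and this call was lost with an estimated correlation (adjusted p = 0.637). Quasi-binomial regression called 8 members higher, DESeq2 6, Fisher's exact test 10 and limma 0. Without METTL3-3KR replicate 1 edgeR called 5 members higher, and 6 to 8 without any other library. Their RNA coverage did not move together: it rose for ATF3, KLF6, DUSP5 and NR4A2 and fell for FOS and ZFP36L1 (limma).

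**Figure D3:**
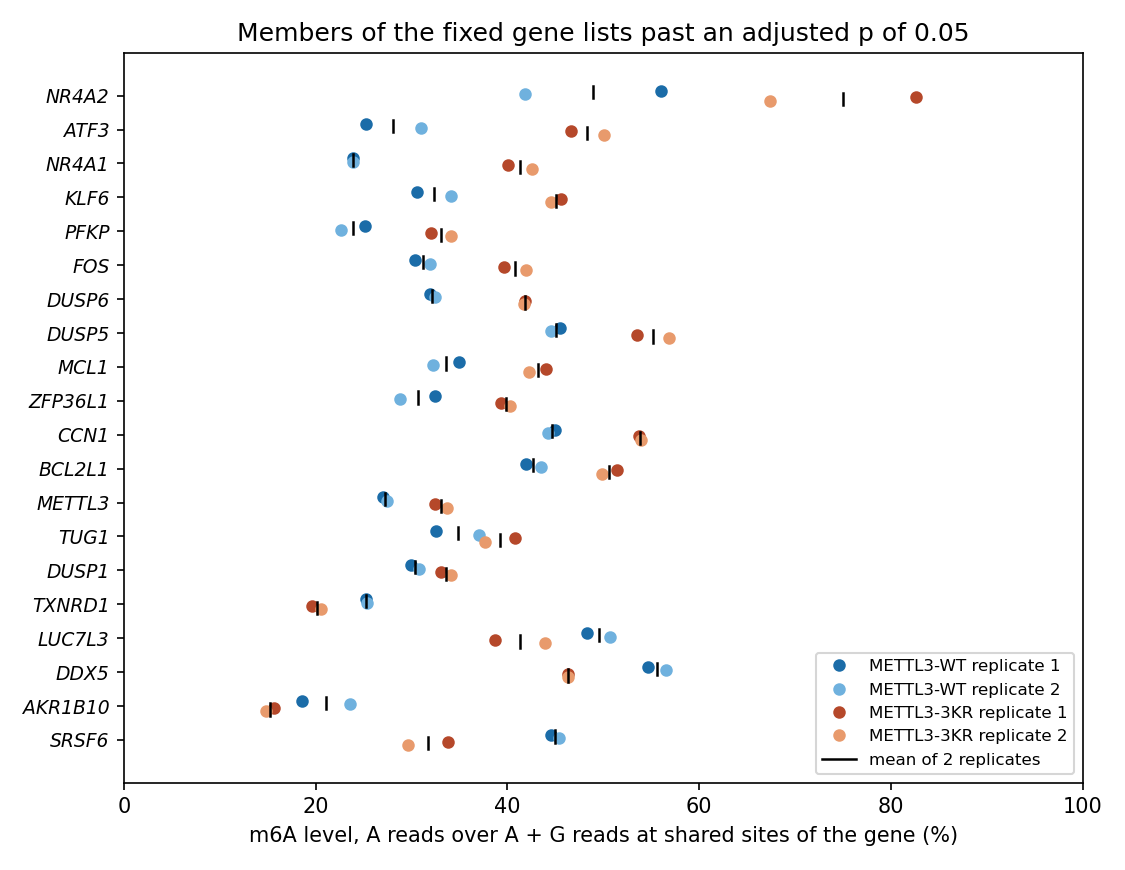
Points give the m6A level (%) of each library, A reads over A plus G reads summed over the shared sites of a gene, for the 20 members of the fixed gene lists that edgeR called, and black bars the mean of the 2 replicates. METTL3-3KR points lie to the right of METTL3-WT points for 15 genes and to the left for TXNRD1, LUC7L3, DDX5, AKR1B10 and SRSF6.

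Splicing factor and NRF2 target genes held a few called falls, while 12 of 24 and 12 of 18 genes tested had a positive change. Of 24 splicing factor and nuclear speckle genes tested, 0 were called higher and 3 lower. These were SRSF6, the RNA helicase DDX5 (55.6% ± 1.28 to 46.3% ± 0.00705 over 4 sites, all lower, edgeR adjusted p = 1.63e-12) and LUC7L3 (49.5% ± 1.66 to 41.3% ± 3.68). The DDX5 change went from -0.54 to -0.24 log2 odds after thinning to equal coverage per site. Adjusted over the list alone the counts were 2 higher, SRSF4 (26.4% ± 4.60 to 42.6% ± 13.1) among them, and 4 lower. Of 18 NRF2 targets tested, TXNRD1, the cytosolic thioredoxin reductase, fell from 25.3% ± 0.104 to 20.1% ± 0.624 and AKR1B10, an aldo-keto reductase, from 21% ± 3.54 to 15.2% ± 0.566. Adjusted over this list alone, AKR1C1 (26.9% ± 2.62 to 32.7% ± 0.919) was also called, as higher, giving 1 higher and 2 lower. TXNRD1 was called without any 1 library and AKR1B10 only without METTL3-WT replicate 1 (-0.56 log2 odds, and -0.34 without METTL3-WT replicate 2), and SLC7A11 stood at 20.8% ± 0.180 and 23.6% ± 1.45. Fisher's exact test called 2 splicing factor genes higher and 4 lower, and 3 NRF2 targets higher and 2 lower. Neither list differed from the other genes by camera (adjusted p = 0.856 for both, and 0.877 with an estimated correlation). The splicing list had a positive median change, a negative mean and a camera direction of down, and the NRF2 list was positive in median and mean with a direction of up.

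Single members of further lists were called higher. BCL2L1 (42.7% ± 1.08 to 50.6% ± 1.06) and MCL1 (33.6% ± 1.85 to 43.2% ± 1.28), both anti-apoptotic BCL2 family genes, rose among 20 lung cancer growth genes tested. On this list the receptor kinase gene MET stood at 33.7% ± 0.135 and 36.6% ± 3.04 and ARID1A at 41.7% ± 9.54 and 23.8% ± 5.30. The matricellular gene CCN1 (44.6% ± 0.564 to 53.8% ± 0.126) rose and was the 1 call among 19 TGF-beta and epithelial-mesenchymal transition genes. Adjusted over this list alone, 4 were higher, CCN1, ITGAV (17.7% ± 1.52 to 22.4% ± 0.159), THBS1 (35.6% ± 1.09 to 38.5% ± 1.2) and ZEB1 (36.2% ± 10.0 to 58.2% ± 12.5). The phosphofructokinase gene PFKP (23.9% ± 1.79 to 33.1% ± 1.43) was the 1 call among 13 hypoxia and glycolysis genes. The long noncoding RNA TUG1 (34.8% ± 3.20 to 39.2% ± 2.19 over 45 sites) was the 1 call among 13 nuclear long noncoding RNAs, where NEAT1 stood at 25.6% ± 0.551 and 24.7% ± 0.902. Among 7 m6A writers METTL3 was the 1 called, and METTL14 (31.1% ± 4.08 and 39.5% ± 3.40), ZC3H13 (33.6% ± 11.8 and 48.3% ± 10.6) and WTAP (40.4% ± 0.389 and 32.9% ± 7.51) did not pass. CCN1 and PFKP were called in none of the 4 fits that left out a library, TUG1 only without METTL3-WT replicate 2 (0.27 log2 odds, 0.42 in that fit and 0.13 without METTL3-WT replicate 1), and MCL1 only without METTL3-WT replicate 1. BCL2L1 lost its call without METTL3-WT replicate 1 or METTL3-3KR replicate 1. Uncalled members that were lower included EPAS1 (48.9% ± 3.38 and 40.5% ± 4.4) and ENO1 of the hypoxia list and SNHG14 (20.3% ± 0.979 and 16.7% ± 2.82) of the noncoding RNA list, and ADM and LINC-PINT were higher. Adjusted over each list alone the counts for the lung cancer, hypoxia, noncoding RNA and writer lists were 2, 1, 1 and 1 higher and 0 lower.

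The remaining lists held no edgeR call, over all genes or over the list alone, and their members went both ways. Of 10 m6A readers and erasers 6 had a positive change, among them IGF2BP1 (17.4% ± 0.406 and 29.2% ± 0.301), YTHDF3 and FTO, while YTHDF2 (59.8% ± 3.01 and 53.3% ± 6.28) was lower. Of 14 acetyltransferases, deacetylases and acetyl-lysine readers 9 had a positive change, KAT2A (32.4% ± 0.878 and 39.4% ± 1.40) among them, while BRD3 (34.8% ± 15 and 26.5% ± 6.83), KAT6B and CREBBP were lower. Of 20 histone methylation and Polycomb genes 13 had a positive change, among them NSD2 (44.9% ± 3.01 and 57.1% ± 6.46) and SETDB1, while KDM4A (64.9% ± 2.7 and 57.8% ± 0.802) and KDM3A were lower. Of 12 DNA damage response genes 9 had a positive change, among them ATRX (36.1% ± 0.486 and 40.0% ± 0.497) and ATR, while RAD50 (32.2% ± 3.11 and 24.5% ± 1.59) and XRCC6 were lower. Of 7 interferon and NF-kB response genes 6 had a positive change, among them NFKBIZ (15.7% ± 2.04 and 23.6% ± 0.0798), IRF2 and STAT2, while BIRC3 (38.5% ± 9.19 and 28.5% ± 4.95) was lower. Of 3 replication-dependent histone genes H2AC11 (14.3% ± 3.94 and 30.8% ± 17.0) and H4C8 were higher and H3C2 (21.7% ± 0.852 and 20.2% ± 0.321) lower, and of 3 alveolar and lung epithelial genes KRT7 (12% ± 1.09 and 14.5% ± 1.06) was higher and KRT8 (48.9% ± 3.00 and 36.4% ± 3.55) and ABCA3 lower. Of 17 cell cycle and mitosis genes 12 had a positive change, among them PRC1 (24.3% ± 2.19 and 35.5% ± 6.37) and ASPM, while RRM2 (48.0% ± 1.59 and 28.8% ± 3.23) and KIF20B were lower. In that order 0, 1, 1, 2, 1, 1, 0 and 1 members had an unadjusted edgeR p under 0.05, and Fisher's exact test called 0, 0, 1, 2, 1, 0, 0 and 1, all higher, while quasi-binomial regression, DESeq2 and limma called 0. No member of the fibroblast list or of the blood and endothelial list had sites enough to be tested. No list other than the immediate-early one passed camera (lowest adjusted p = 0.856), except the interferon and NF-kB list at a coverage minimum of 50 (adjusted p = 0.0228, and 0.673 with an estimated correlation). Median changes of the acetylation, Polycomb and nuclear noncoding RNA lists were positive while their camera directions, taken against other genes, were down, and the Polycomb mean was negative.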

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

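The gene coverage tests below were chosen only after the tables had been seen. So was the use of U6 odds, METTL3 RNA and background to weigh explanations of levels at shared sites, although background subtraction itself was a planned setting. The coverage value per gene, which no comparison of levels uses, differed between the genotypes. METTL3 coverage was 1.68-fold higher in METTL3-3KR. In all, 482 of 5602 genes had a higher and 384 a lower coverage value in METTL3-3KR (limma, adjusted p under 0.05), with no untreated or parental sample to set beside them.

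Levels at shared sites were higher in METTL3-3KR by 1.86 percentage points at the median, and 3 explanations were weighed. Unconverted background at sites with no gene was higher in the METTL3-WT libraries (1.3% and 1.75%, against 0.969% and 0.982%). A background of this order would raise the METTL3-WT levels, which argues against it. The subtraction used each site's own conversion fraction, per gene for sites in genes, and widened the difference to 2.37 points. Given the values at sites with no gene, this could be foreseen in part, so the subtraction is no independent test. A loss of modified reads by the same factor at every site would move the odds of all sites alike, but over the 4 pairs of libraries log2 odds at 256 U6 sites changed by at most -0.0638 and at protein-coding sites by at least 0.08 (gap of at least 0.18, against at most 0.07 between replicates). The bound set beforehand, on U2 level ratios, was met in 3 of 4 pairs, and U2 odds rose by 0.47 to 0.70, so an effect on some sites that METTL3 is not known to modify stays open. Whether the genotype or the 1.68-fold higher METTL3 RNA, which may mean a higher dose of enzyme, goes with the higher levels cannot be told apart, because METTL3 coverage differed between the genotypes in every pair of libraries.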

How the results depend on the processing

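Restriction to protein-coding and long noncoding RNA genes, the authors' P of at most 1e-10, minimums of 10 and 20 A reads and the well-measured subset were chosen after the data were seen. None of the 33 named genes that were called and no difference in median level over all shared sites, at promoters, upstream antisense or in distal intergenic sites changed sign. Of 47 named genes that were not called, 4 did: BRD3 (0.21 log2 odds without METTL3-WT replicate 1), KAT6B (0.46 at a coverage minimum of 50), BIRC3 (0.19 at a coverage minimum of 15) and H4C8 (-0.03 without METTL3-3KR replicate 2), none past the threshold, and 23 other values of uncalled genes passed it, with the same sign. The ratio of unassigned sites, METTL3-WT over METTL3-3KR, went from 2.04 to 0.839 with at least 20 A reads and 0.811 at an authors' P of at most 1e-10, and sites listed in 1 genotype only turned from 4430 and 5614 to 4490 and 4429 after thinning. Camera directions changed under at least 1 alternative for 9 of 16 lists, of which 0 were called. For the 33 called genes, 276 of 347 values under other settings and 73 of 132 with a library left out stayed past the threshold, and 71 and 59 fell short of it with the same sign. Listed sites for METTL3-WT replicates 1 and 2 and METTL3-3KR replicates 1 and 2 were 42292, 69352, 35156 and 36553 at a coverage minimum of 50, 104702, 152334, 83265 and 86462 at a level minimum of 0.2, 32631, 29314, 36630 and 39271 at an authors' P of at most 1e-10, 36400, 41704, 36304 and 39430 with at least 10 A reads, and 15738, 14794, 16642 and 18494 with at least 20. Sites listed in 1 genotype only (METTL3-WT, METTL3-3KR) were 1448 and 2374 at a coverage minimum of 50, 2296 for METTL3-WT at a level minimum of 0.2, 679 and 1070 in genes with a median coverage of at least 50, 13 and 40 among well-measured sites, and 6865 to 300685 and 9089 to 116040 with a library left out. All of these use fewer sites, or fewer libraries. The median level difference was 2.48 points with coverage weighting, 2.37 after background subtraction and 1.43 over all listed sites. The promoter difference was 3.72 (coverage weighting), 2.78 (all listed sites) and 0.964 points (500 bp window), and the distal intergenic one 6.08 (coverage of at least 50) and 0.438 points (coverage weighting). Over all sites and at promoters, coverage weighting gives great weight to U2 copies such as RNU2-23P (352407 to 494275 reads per library). The cause of the other moves was not tested. Sites called higher and lower were 130 and 32 at a coverage minimum of 50 (fewer sites tested), 786 and 293 by Fisher's exact test (no spread between replicates), 0 and 0 by limma, 0 and 0 by quasi-binomial regression, and 23 and 7 in protein-coding and long noncoding RNA genes. Sites called higher were 33 after centring, 28 with a difference of at least 10 points and 38 after thinning. Leaving out a library gave 21 to 29 higher and 2 to 7 lower. Genes called higher and lower were 48 and 14 by DESeq2, which gave no adjusted p for 4016 genes, 356 and 125 by Fisher's exact test, 0 and 0 by limma, and 31 to 57 and 8 to 29 with a library left out; genes called higher were 69 after centring and 71 in protein-coding and long noncoding RNA genes. With 1 library in an arm, that library is assumed to vary like the others. On simulated changes limma called 0 genes too, so its counts say little. A replicate block gave 144 sites higher and 41 lower and 97 genes higher and 42 lower. Deviations of libraries with the same number were hardly correlated across sites (0.00933) or genes (0.02). Counting error in the reads also lowers such correlations, so they cannot show whether the libraries were paired. Of the lists, 2 passed at a coverage minimum of 50, and 0 with an estimated correlation, where the immediate-early list had an adjusted p of 0.637. DRACH-only versions and results by motif were not run. Simulated changes of 1 log2 unit were recovered for 22% of sites and 68% of genes. The changed ones had a mean of at least 50 reads per library, and what part depth has in recovery was not tested.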

Other observations

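The comparison of gene coverage, the listed sites at a stricter P or with more A reads, the recurrence of unassigned sites, the coverage of shared sites and the coverage of immediate-early genes were tests chosen after the result was seen. The chromatin-associated RNA of replication and mitosis genes had lower coverage values in METTL3-3KR. Of 18 cell cycle genes with a value, 0 were higher and 12 lower (limma), with log2 coverage falling by 0.84 ± 0.09 (SE) for the topoisomerase TOP2A, by 0.70 ± 0.08 for the replicative helicase subunit MCM4, by 0.60 ± 0.08 for the replication clamp PCNA and by 0.43 ± 0.09 for the proliferation marker MKI67. All 3 replication-dependent histone genes with a value were lower, H2AC11 by a log2 change of -1.19 ± 0.12 and H3C2 by -1.07 ± 0.17. Against other genes both lists moved down by camera (adjusted p = 1.42e-08 and 0.00132). So did the DNA damage response list (0 higher and 2 lower of 15) and the splicing factor list (2 higher and 7 lower of 25), each with an adjusted p of 0.0348. With an estimated correlation, a version that can hardly pass with 4 libraries, these calls were lost (camera adjusted p = 0.351, 0.653, 0.744 and 0.744). Among immediate-early genes 5 rose and 9 fell, EGR1 with a log2 change of -0.81 ± 0.12. The largest rises were in UGT1A9, a glucuronosyltransferase (10.5-fold), ATF3 (3.12-fold), RANBP1 (2.91-fold) and TIPARP (2.84-fold). The largest falls were in the pseudogenes LOC110467535 (0.329-fold), LOC110467533 (0.332-fold) and LOC110467538 (0.340-fold) and the 18S ribosomal RNA pseudogene RNA18SP5 (0.351-fold), and a difference in residual ribosomal RNA between the libraries was not tested. Across 5053 genes the change of level and the change of coverage had a Spearman correlation of -0.0443, and genes are not independent replicates.

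More sites with no gene assigned were listed in the METTL3-WT libraries, 2.04 times as many on average as in METTL3-3KR. For sequencing depth, the ratio of median coverage at shared sites, METTL3-WT over METTL3-3KR, was 0.936. As 20532 of the 24352 shared sites were in genes, this does not measure depth at unassigned positions. Unassigned sites with at least 50 reads numbered 21324 and 44960 in the METTL3-WT libraries and 15788 and 15001 in the METTL3-3KR libraries. Loss of methylation at such sites in METTL3-3KR cannot be told apart from background: sites listed in both libraries of a genotype were not more frequent in METTL3-WT (ratio 0.949), but with 4.85% and 2.66% of sites recurring between its libraries, a position with few A reads need not recur. At an authors' P of at most 1e-10, which itself uses the background, the ratio of mean unassigned sites per library fell to 0.811, as it did for sites in genes (from 1.19 to 0.818). With at least 10 and 20 A reads it was 1.39 and 0.839, while it stayed at 2.15 at a coverage minimum of 50, 1.89 at a level minimum of 0.2 and 2.58 after thinning. These means lean on METTL3-WT replicate 2. After thinning, unassigned sites numbered 122390 and 268638 in METTL3-WT replicates 1 and 2, and 86856 and 64825 in METTL3-3KR. Unconverted background in the METTL3-WT libraries is thus a candidate explanation for the sites with few A reads. Methylation or read depth that differs at unassigned positions with few A reads stays open.

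The rise of levels in immediate-early genes was set against 3 explanations. A shift of reads between sites of a gene was tested by thinning each site to equal coverage, which left 8 of the 9 called members past the threshold. A library-wide shift of levels was tested by centring, which left 7 of 9. For a change in the RNA coverage of these genes, 4 of the 9 called members rose and 2 fell in coverage. These counts show no shared direction. They cannot decide on this explanation, because coverage need not change in the same direction in every gene. The thinning and centring values argue against a shift of reads and a library-wide shift, each as the whole cause. A change in RNA coverage stays open. So do the METTL3 form, the METTL3 RNA difference of 1.68-fold and other differences between the 2 cell populations, which were not separated.

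Of the 3 ways to split the 4 libraries into 2 and 2, only 1, the real one, called as many genes as the 153 reported, and the highest of the others called 0. With 3 splits no share under 0.05 is possible. Each of the other splits also puts 1 library of each genotype in each arm. Any difference between the genotypes then adds to the spread within arms. The 0 calls there could be foreseen, so they are no support for the 153.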
